A study of Mus musculus with 6 samples.

How the data were processed

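Gene expression was measured with 6 arrays of RNA from tumours grown under the skin of SCID mice from NCI-H2228, a human lung adenocarcinoma cell line that carries the EML4-ALK fusion gene. The mice had received the ALK inhibitor CH5424802, later named alectinib, by mouth at 4 or 20 mg/kg, or its vehicle, and tumours were taken 6 h later. Each of the 3 groups has 2 arrays. The labels do not say that the 2 arrays of a group come from separate animals, so p-values measure only the spread between these arrays, which may be technical. The labels give mouse as the organism, while the array carries probe sets for human genes, so the values describe mainly the human tumour cells. How mouse transcripts affect them was not measured here.

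The authors deposited 1 table of intensity values on a linear scale, with 1 column per array and 54675 probe sets. It was made with GCRMA in R 2.10.0, per the submitters' processing notes. GCRMA corrects the background by probe sequence, makes the distributions of arrays alike by quantile normalization and summarises the probes of a set by median polish. Which arrays were normalized together is not given in the sources used here. The lowest intensity was 4.578 in every array, and between 39.48% and 40.19% of probe sets lay at that floor. Changes of genes near the floor are therefore understated. Median polish also gives exactly equal values in different arrays: 3316 of 10271 tested genes, 32.3%, had the same value (within 1e-06 log2 units) in both arrays of at least 1 group, and 531 had it in all 3 groups. The medians of the 6 deposited columns ran from 5.024 to 5.151.

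Intensities were converted to log2, as was fixed for values on a linear scale. Gene names came from the platform annotation, which can be old: 41097 probe sets had 1 gene, 1801 had several and 11777 had none listed. Each gene was represented by the single-gene probe set with the highest mean over the 6 arrays, and genes with a mean log2 value under 4 were left out, leaving 10271 of 19775 genes. A linear model over all 6 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 3 contrasts: 20 mg/kg against vehicle, 4 mg/kg against vehicle and 20 mg/kg against 4 mg/kg. The tests are two-sided, and p-values were adjusted over all genes by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. The model had 3 residual degrees of freedom and 0.723 prior degrees of freedom, so the moderation drew little on other genes. Without the 531 genes tied in all 3 groups, a fit added after seeing the data, the prior degrees of freedom were 1.44. The ties thus lower the moderation. The small number of arrays limits the precision. Each SE is limma's moderated SE, from a spread pooled over all 3 groups and drawn towards a prior SD of 0.0418 log2 units. The median residual SD was 0.1351. An SE is therefore not the spread of the 2 compared groups alone. A change against a group within 1 log2 unit of the floor is given as at least N-fold.

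The 36 gene lists were fixed before the data were examined, as were the 3 comparisons, the threshold and the alternatives tried, except those named as added. Of these lists, 34 had at least 5 tested genes and were tested with camera (inter-gene correlation preset at 0.01, Benjamini-Hochberg over the lists). Beside it stand camera with an estimated correlation and fry. With an estimated correlation camera has only the 3 residual degrees of freedom and so little power with these arrays. The estimates also differed from the preset 0.01: they were 0.55 for mitosis, 0.41 for hypoxia and 0.31 for glycolysis genes. For MAPK pathway output, FOXO targets and mesenchymal genes they were 0.08, 0.05 and -0.04. A higher correlation weakens the evidence for a list, so a lost call is not a matter of power alone. The lowest adjusted p with an estimated correlation, over all lists and comparisons, was 0.251. Failing this test therefore does not decide for or against a list. Genes are named by a rule fixed at the same time: the 10 largest rises and falls past the threshold whose arrays do not overlap between the groups for each dose against vehicle, and the 5 of each for 20 against 4 mg/kg. Where fewer than 5 passed, the smallest p-values in that direction fill up to 5, as values that did not pass. For each list past its test, up to 4 members that passed are named, or the 2 with the largest change where none passed. A further 17 genes of ALK signalling may be named whatever their result. Of these, ETV4 lay under the level filter (mean log2 2.22) and BCL3 was not analysed here. Genome coordinates were not used here.

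The chance relation between the 2 dose effects, which share their vehicle arrays, was simulated in 100 draws of unchanged groups. Simulated counts of shared genes and of shared signs among the genes with the smallest p-values, as many as were called, were added after seeing the data, with no effect at either dose and with the observed effect at 20 mg/kg alone. The steps were tested on simulated data with the means and residual spreads of the 10271 genes, with 200 genes changed in the comparison of 20 mg/kg with vehicle. In 20 draws the fit called 20.1% of genes changed by 0.5 log2 units, 39.6% of those changed by 1 and 72.8% of those changed by 2, and 7.3% of its calls were false, somewhat above the threshold's nominal share. Alternatives were: no or a stricter level filter (mean log2 of at least 6), quantile normalization, centring each array on its median, the mean of all probe sets of a gene, probe sets that may cross-hybridise left out, every probe set on its own, the next probe set of a gene, a mean-variance trend with a robust prior, array weights, the replicate number as a block, log2(value + 16), only the 4 arrays compared, and each array left out in turn. Where that leaves a group with 1 array, the lone array is assumed to vary like the other groups. Leaving out an array of the group outside a comparison changes no mean in it. This alters only the estimate of the spread and gives the same fit as the 4 compared arrays alone. Leaving out genes with equal values within groups, and crossing the replicate numbers, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.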

Results

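The data are expression levels of human genes in NCI-H2228 tumours 6 h after an oral dose of vehicle, 4 mg/kg or 20 mg/kg of CH5424802, an inhibitor of the ALK kinase, with 2 arrays in each of the 3 groups. Intensities reached between 42429 and 47036 in the 6 arrays. Across the 10271 tested genes the 2 arrays of a group correlated at r = 0.992 for vehicle, 0.995 for 4 mg/kg and 0.997 for 20 mg/kg (across genes, which are not independent replicates). Between arrays of different groups r ran from 0.972 to 0.992, the highest for vehicle replicate 1 with 4 mg/kg replicate 1. The first principal component held 58.1% of the variance and ordered the groups by dose, with vehicle replicate 2 at -34.8, vehicle replicate 1 at -18.9, the 4 mg/kg arrays at 3.5 and 4.59 and the 20 mg/kg arrays at 21.9 and 23.7. A control probe set for 18S ribosomal RNA read 1713 and 4058 in the vehicle arrays, 489 and 374 at 4 mg/kg and 573 and 637 at 20 mg/kg. Both vehicle arrays thus lay above all treated arrays, so each comparison with vehicle carries this difference, whose cause was not tested. Vehicle replicate 2, with the highest reading, also lay furthest out on the first component.

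Comparing 20 mg/kg with vehicle asks how the tumours' transcripts differ after the higher dose. The largest fall was in DUSP6, a phosphatase that ERK signalling induces and that inactivates ERK: its mean intensity was 13076 with vehicle and 295 at 20 mg/kg, 44.3-fold lower (log2 change -5.47, SE 0.15, adjusted p = 0.0104, n = 2 arrays per group). The early response gene IER3 fell 12.4-fold (log2 -3.64, SE 0.09), the chemokine CX3CL1 12.4-fold (log2 -3.63, SE 0.15) and cyclin D1, CCND1, which drives entry into the cell cycle, 11.8-fold (log2 -3.56, SE 0.26). KLHL24, a kelch-like protein, rose 7.16-fold (log2 2.84, SE 0.05, adjusted p = 0.00758). In all, limma called 445 genes, 232 higher and 213 lower, of which 115 and 106 changed at least 2-fold.

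Genes of MAPK pathway output, the transcripts that follow ERK activity, fell together: 13 of the 17 measured fell and the other 4 did not pass (16 fell when adjusted over the list alone), with a mean log2 change of -2.30. camera gave an adjusted p of 3.61e-15 for the list, and an adjusted p = 0.335 with an estimated correlation. Beside DUSP6, IER3 and CCND1 they included PHLDA1 (log2 -2.89, SE 0.19), the pathway inhibitor SPRED1 (log2 -2.87, SE 0.23) and the transcription factor ETV5 (log2 -2.72, SE 0.06). MYC, which the list also holds, fell by 2.56 on the log2 scale (SE 0.15). The feedback inhibitors SPRY4 (log2 -1.37, adjusted p = 0.0543) and SPRY2 (log2 -1.55, adjusted p = 0.122) did not pass, nor did EGR1 (log2 -0.30, adjusted p = 0.421), which fell without vehicle replicate 1 (-0.55, adjusted p = 0.0328) and was at -0.06 without vehicle replicate 2. The other large falls were in the chromatin protein HMGA2 (log2 -3.31, SE 0.31), the transcription factor MAFF (log2 -3.17, SE 0.14), the ion channel TRPM8 (log2 -3.11, SE 0.13) and the cytokine IL6 (log2 -3.08, SE 0.20).

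**Figure D1:**
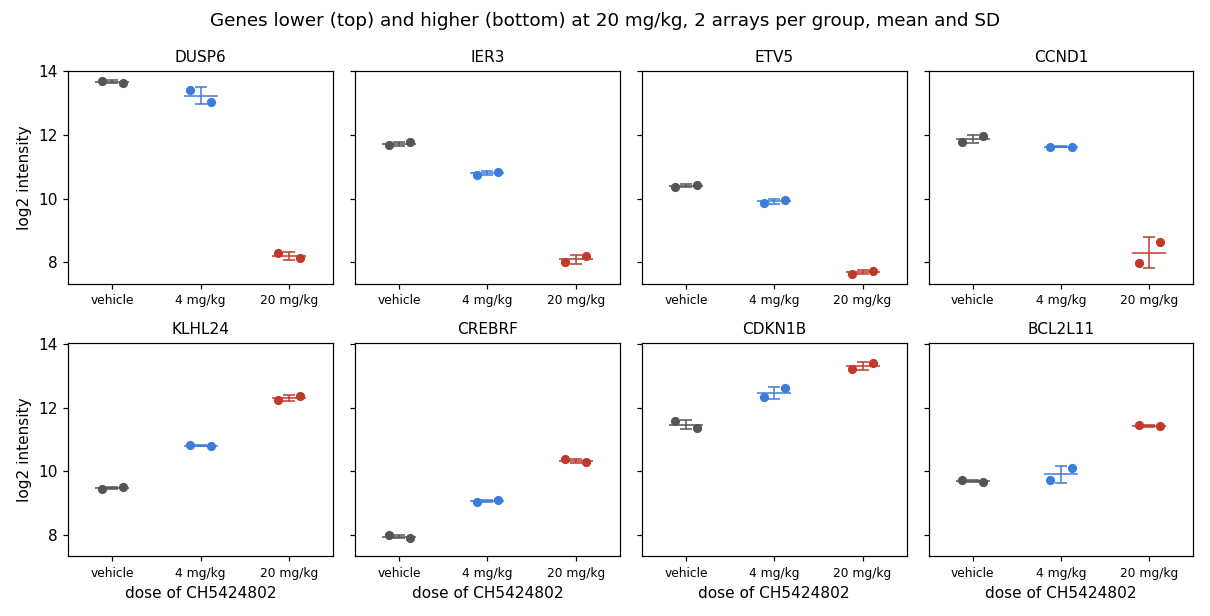
Points are the log2 intensity (vertical axis) of 8 genes in each array at each dose of CH5424802 (horizontal axis), with bars for the group mean and SD of 2 arrays. DUSP6, IER3, ETV5 and CCND1 are lower at 20 mg/kg than at either other dose, and KLHL24, CREBRF, CDKN1B and BCL2L11 are higher.

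Targets of the FOXO transcription factors, which AKT signalling holds out of the nucleus, were higher: 5 of the 19 measured rose and 14 did not pass (10 rose when adjusted over the list alone), with a mean log2 change of 0.78. camera gave an adjusted p of 1.75e-05, and an adjusted p = 0.52 with an estimated correlation. They included the ubiquitin ligase FBXO32 (log2 1.88, SE 0.19), the cell cycle inhibitor CDKN1B (log2 1.84, SE 0.14), the cell death gene BCL2L11, or BIM (log2 1.73, SE 0.14), and SESN3 (log2 1.48, SE 0.12). With their next brightest probe sets BCL2L11 was at -0.06 and SESN3 at 0.19, neither past the test. ERBB3 (log2 0.98, adjusted p = 0.0803) and IRS2 (log2 -0.79, adjusted p = 0.183, and -0.46 without vehicle replicate 2) did not pass. Over the alternatives ERBB3 ran from 0.43 to 1.16 and IRS2 from -1.12 to -0.26. The largest rises outside the list, beside KLHL24, were APOLD1 (log2 2.98, SE 0.35), GRAMD1C (at least 7.54-fold, with vehicle near the floor), GTF2H2B (log2 2.64, SE 0.20) and GLCCI1 (log2 2.55, SE 0.16). SOX2, a transcription factor of stem and airway cells, also rose (log2 2.44, SE 0.18), as did LRRC31 (log2 2.44, SE 0.15), the polarity gene PARD6B (log2 2.39, SE 0.22), CREBRF (log2 2.38, SE 0.05) and the collagenase MMP13 (log2 2.37, SE 0.18).

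Among STAT3 targets 5 of 23 fell (9 fell and 2 rose when adjusted over the list alone), including NNMT (log2 -2.36, SE 0.26) and CEBPD (log2 -1.87, SE 0.18) beside CCND1 and MYC, which the MAPK list also holds. For this list camera gave an adjusted p of 0.00275, and an adjusted p = 0.698 with an estimated correlation. SOCS3, a feedback inhibitor that STAT3 induces, was at log2 -2.66 (adjusted p = 0.0748), or -0.32 with its next brightest probe set and -0.75 with the mean of its probe sets. STAT3 itself was at -0.22 (adjusted p = 0.335). NF-kB and inflammatory cytokine genes had 4 of 20 lower, IL6, CXCL8 (log2 -2.34, SE 0.25), PTGS2 (log2 -1.99, SE 0.25) and CXCL1 (log2 -1.48, SE 0.17). Their list had an adjusted p of 0.00287, and an adjusted p = 0.698 with an estimated correlation. The immediate early list had 4 of 17 lower, IER3, MAFF, CCN1 (log2 -1.12, SE 0.12) and KLF6 (log2 -1.10, SE 0.12). Its adjusted p was 0.0235, and an adjusted p = 0.707 with an estimated correlation. This call was lost without 20 mg/kg replicate 2 (mean -0.66). It was lost too without either 4 mg/kg array, which leaves the mean at -0.65 and changes only the estimate of the spread.

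Hypoxia response genes, which low oxygen induces, had 3 of 21 lower (11 when adjusted over the list alone), with a mean log2 change of -0.61: BHLHE40 (log2 -2.16, SE 0.16), ADM (log2 -1.21, SE 0.10) and ANGPTL4 (log2 -1.16, SE 0.03). Glycolysis genes had 2 of 17 lower (7 when adjusted over the list alone), the hexokinase HK2 (log2 -2.28, SE 0.04; -0.76 as the mean of its probe sets, the others being at the floor) and the glucose transporter SLC2A3 (log2 -1.66, SE 0.07). Of 11 acute phase genes the haptoglobin gene HP fell (log2 -1.69, SE 0.14). The adjusted p from camera was 1.5e-05 for hypoxia, 3.15e-05 for glycolysis and 0.000858 for acute phase genes, and with an estimated correlation the adjusted p = 0.707 for hypoxia and 0.698 for the others. The 18S control probe set was also lower in these arrays, at 573 and 637 against 1713 and 4058 with vehicle.

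Ribosome biogenesis genes had 1 of 22 lower, NOP16 (log2 -1.28, SE 0.07), with a list mean of -0.53 and an adjusted p of 0.000405 (adjusted p = 0.698 with an estimated correlation). Among fatty acid synthesis genes ELOVL6 fell (log2 -0.52, SE 0.02; 1 of 10), and among 18 cholesterol synthesis genes none passed, with SQLE at log2 -1.08 and SC5D at 0.98. Their camera adjusted p was 0.0246 and 0.0235 (adjusted p = 0.707 and 0.81 with an estimated correlation). The fatty acid mean of -0.32 became -0.03 without probe sets that may cross-hybridise (adjusted p = 0.319). That call was also lost without vehicle replicate 1 (mean -0.25, adjusted p = 0.285), after quantile normalization, with centred arrays, with the stricter filter and with the replicate block. The cholesterol call was lost without vehicle replicate 2 (mean -0.22, adjusted p = 0.0555), with the stricter filter (-0.24) and without probe sets that may cross-hybridise (-0.20). Mitosis genes were higher as a list, with TOP2A the 1 of 27 that rose (log2 1.47, SE 0.15) and an adjusted p of 0.0421 (adjusted p = 0.81 with an estimated correlation). Its mean of 0.30 became 0.19 without 20 mg/kg replicate 2 (adjusted p = 0.248), and the call was also lost without vehicle replicate 1 (0.32) or vehicle replicate 2 (0.29). ALK and EML4, the partners of the fusion, were at log2 -0.08 (SE 0.12) and 0.04 (SE 0.11), and PIM1 was at log2 0.00 (SE 0.12). EML4 was at -0.04 without vehicle replicate 1, ALK at -0.14 without vehicle replicate 2, and PIM1 at -0.15 and 0.15 without vehicle replicate 1 and vehicle replicate 2, none past the test. None of 10 fibroblast markers or 7 macrophage and leukocyte markers passed. Such host cells are of the mouse, and how their transcripts read on this human array was not measured. The result therefore does not show that they were unchanged.

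In all, camera called 12 of 34 lists, 2 higher and 10 lower, and none of them in any comparison held with an estimated correlation. fry called 14 lists, 10 of these 12 among them, but not mitosis (fry adjusted p = 0.403) or cholesterol synthesis (fry adjusted p = 0.14). The gene count was 802 without vehicle replicate 1, 104 without vehicle replicate 2, 136 without 4 mg/kg replicate 1 or replicate 2, 19 without 20 mg/kg replicate 1 and 5 without 20 mg/kg replicate 2. It was 57 with no level filter, 285 without probe sets that may cross-hybridise and 93 with the replicate number as a block. Without genes tied in all or any groups it was 819 and 1242, after quantile normalization 1536 and with centred arrays 1958. With the 4 compared arrays alone it was 136, the same fit as without either 4 mg/kg array. With the next brightest probe set, 10 of 30 named values kept their direction and lost their call: KLHL24 (log2 1.89), CREBRF (1.02), SESN3 (0.19), TOP2A (0.64), SPRED1 (-0.67), CCN1 (-0.77), NNMT (-2.41), NOP16 (-0.51), ELOVL6 (-0.03) and BHLHE40 (-2.59). With the mean of all probe sets of a gene the FOXO list's mean was 0.44 and the glycolysis list's -0.325, both still called, and genes that moved less but were still called included SOX2 (0.98), FBXO32 (0.91), BCL2L11 (0.54), SESN3 (0.48), TOP2A (0.70), MAFF (-1.76), TRPM8 (-1.57), SPRED1 (-1.35), ETV5 (-1.50), NOP16 (-0.45) and ELOVL6 (-0.18). Larger with the next brightest probe set were GLCCI1 (4.03), CXCL8 (-5.05), PTGS2 (-3.15) and KLF6 (-1.93), and smaller SOX2 (1.12), all still called. The acute phase mean was -0.35 without probe sets that may cross-hybridise, still called, and with log2(value + 16) GRAMD1C lost its call (log2 1.78, adjusted p = 0.0683) while ANGPTL4 (-0.61) and SLC2A3 (-1.004) kept theirs.

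Comparing 4 mg/kg with vehicle asks the same of the lower dose. limma called 6 genes. KLHL24 rose 2.53-fold (log2 1.34, SE 0.05), C5orf34 1.98-fold (log2 0.99, SE 0.03) and the peptidase ERAP2 1.81-fold (log2 0.86, SE 0.03). ANGPTL4 fell 2.12-fold (log2 -1.09, SE 0.03), PLAUR, the urokinase receptor, 2.04-fold (log2 -1.03, SE 0.04) and HK2 1.94-fold (log2 -0.96, SE 0.04), each of the 6 with an adjusted p of 0.0485 and n = 2 arrays per group. ERAP2, ANGPTL4 and HK2 had exactly equal values in both arrays of 1 of the 2 groups, as 26% of tested genes had in this comparison, so their SEs rest partly on such ties. The next smallest p-values, which did not pass, were CREBRF (log2 1.12, adjusted p = 0.056) and DCAF12 (log2 0.63) among the higher genes and SLC2A3 (log2 -1.66, adjusted p = 0.0538) and CCDC86 (log2 -0.55) among the lower. Another probe set, the next brightest, read 0.06 for KLHL24, 0.09 for ERAP2 and -0.59 for PLAUR, none past the test, and -0.13 for CREBRF. Without probe sets that may cross-hybridise PLAUR was at -0.04 (adjusted p = 0.701). With the mean of all probe sets KLHL24 was at 0.80, ERAP2 at 0.23, PLAUR at -0.55 and HK2 at -0.32, and with log2(value + 16) ANGPTL4 was at -0.58, none past the test.

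Hypoxia response genes (mean log2 change -0.62, adjusted p = 2.16e-11) and glycolysis genes (mean -0.42, adjusted p = 2.54e-07) were lower as lists at this dose too, and with an estimated correlation the adjusted p = 0.752 for both. In each 1 gene passed, ANGPTL4 and HK2 (12 of 21 and 3 of 17 when adjusted over the list alone). Acute phase genes had a mean of -0.71 (adjusted p = 6.64e-07; adjusted p = 0.752 with an estimated correlation), with 9 of 11 lower when adjusted over the list alone. HP was at log2 -1.77 (adjusted p = 0.0892) and the fibrinogen gene FGG at -1.03 (adjusted p = 0.194). The glycolysis mean was -0.27 with the mean of all probe sets and the acute phase mean -0.47 without probe sets that may cross-hybridise, both still called. The 18S control probe set moved the same way, at 489 and 374 against 1713 and 4058.

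MAPK pathway output genes had a mean log2 change of -0.30 with none of 17 past the test (4 lower when adjusted over the list alone), an adjusted p of 0.000562 from camera and an adjusted p = 0.752 with an estimated correlation. Without probe sets that may cross-hybridise the mean was -0.12 and the call was lost. DUSP6 was at log2 -0.43 (SE 0.15, adjusted p = 0.298), or -0.24 without 4 mg/kg replicate 2 and -0.25 with its next brightest probe set. MYC was at -0.98 (adjusted p = 0.15) and IER3 at -0.93 (adjusted p = 0.114).

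Mitosis genes were higher as a list (mean log2 0.54, adjusted p = 2.61e-05; adjusted p = 0.88 with an estimated correlation), with none of 27 past the test. Their mean was 0.34 without 4 mg/kg replicate 2, still called. TOP2A was at log2 1.75 (adjusted p = 0.113) and CDK1 at 1.28 (adjusted p = 0.166), or 0.90 and 0.21 with their next brightest probe sets. DNA replication genes were higher likewise (mean 0.28, adjusted p = 0.0394; adjusted p = 0.88 with an estimated correlation), again with no member past the test. This call was lost without vehicle replicate 2 (mean 0.19), 4 mg/kg replicate 1 (0.39) or 4 mg/kg replicate 2 (0.17). It was lost too without either 20 mg/kg array (0.28), which changes only the estimate of the spread here. It was also lost with the stricter filter (0.29) and with the mean of probe sets (0.21). CCNE2 was at log2 1.65 (adjusted p = 0.217), or -0.33 with its next brightest probe set, and PCNA at 0.90 (adjusted p = 0.295), or 0.55 without vehicle replicate 2.

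STAT3 targets (mean -0.27, adjusted p = 0.0262) and antigen presentation genes (mean -0.09, adjusted p = 0.0239) were lower as lists, again with no member past the test and an adjusted p = 0.88 with an estimated correlation. SOCS3 was at log2 -1.86, or -0.11 with its next brightest probe set, and LIFR, a cytokine receptor, at 1.82, or 1.13 without vehicle replicate 2. In the antigen presentation list GBP1 was at 1.36, or 0.79 without vehicle replicate 2, and TAPBP at -0.53, or -0.29 without vehicle replicate 2 and -0.28 without 4 mg/kg replicate 1. The mean of the antigen presentation list was 0.02 without 4 mg/kg replicate 1 (adjusted p = 0.242), -0.20 without 4 mg/kg replicate 2 and -0.19 with centred arrays, and its call was also lost without vehicle replicate 1 (-0.12) or vehicle replicate 2 (-0.05). The STAT3 call was lost without vehicle replicate 1 (-0.33), vehicle replicate 2 (-0.20), 4 mg/kg replicate 1 (-0.18) or 4 mg/kg replicate 2 (-0.35), after quantile normalization (-0.30) and with the replicate block. Without probe sets that may cross-hybridise the antigen presentation (-0.04), STAT3 (-0.22) and DNA replication (0.35) calls were lost too.

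In all, camera called 8 lists and fry none, with 7 at an unadjusted p under 0.05. The gene count of 6 is not a measure of how little changed, since 1745 genes had an unadjusted p under 0.05. The count was 475 without vehicle replicate 1, 156 without 4 mg/kg replicate 1 and 0 without any other array. It was 3 with no level filter. It was 0 with the 4 compared arrays alone, with array weights, with the replicate number as a block or with the stricter filter. The mean of probe sets, every probe set tested and log2(value + 16) also gave 0. In the fits that gave 0 limma had 1281 to 1885 genes, or 2564 probe sets, at an unadjusted p under 0.05. Leaving out genes tied in all groups gave 0, genes tied in any group 257 (231 higher and 26 lower), quantile normalization 41 (30 higher and 11 lower) and centred arrays 766 (517 higher and 249 lower), against 3 higher and 3 lower. Without 4 mg/kg replicate 1 camera called 5 lists.

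**Figure D2:**
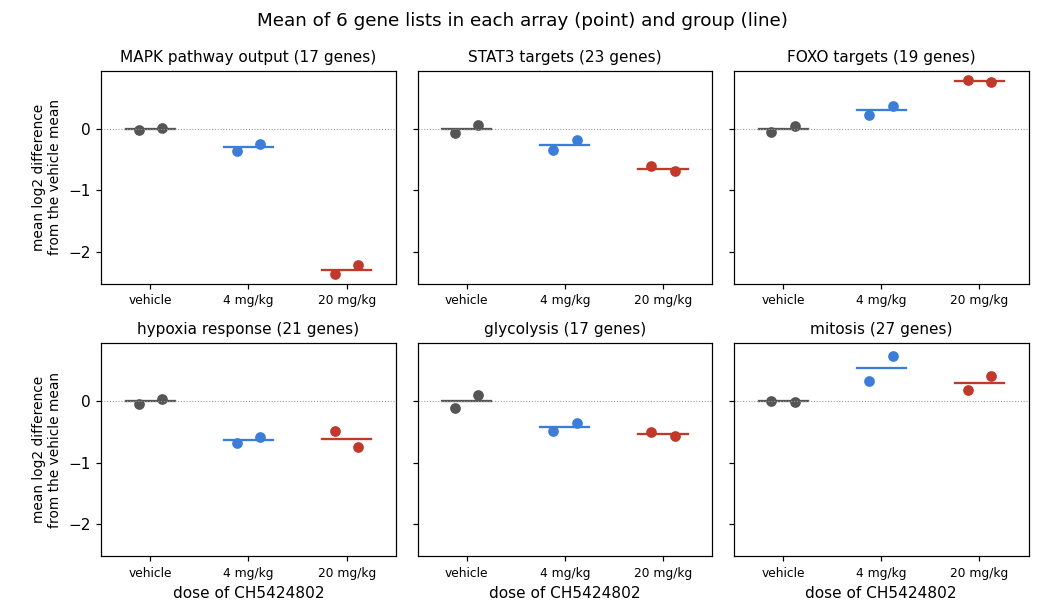
Points are the mean log2 difference (vertical axis) of 6 gene lists in each array from the vehicle mean at each dose (horizontal axis), and lines are the group means of 2 arrays. The MAPK list averages -0.30 at 4 mg/kg and -2.30 at 20 mg/kg, while the hypoxia list averages -0.62 and -0.61.

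Comparing 20 mg/kg with 4 mg/kg asks how the 2 doses differ. limma called 38 genes, 13 higher and 25 lower. DUSP6 was 32.8-fold lower at 20 mg/kg (log2 -5.04, SE 0.15, adjusted p = 0.0211, n = 2 arrays per group), CX3CL1 9.11-fold (log2 -3.19, SE 0.15), IER3 6.54-fold (log2 -2.71, SE 0.09), ANKRD22 5.06-fold (log2 -2.34, SE 0.15) and ETV5 4.69-fold (log2 -2.23, SE 0.06). The cell death gene BMF was 3.58-fold higher (log2 1.84, SE 0.07), KLHL24 2.83-fold (SE 0.05 log2 units) and DDIT4L 2.83-fold (SE 0.06). The cholesterol transporter ABCA1 was 2.5-fold higher (log2 1.32, SE 0.08) and CREBRF 2.4-fold (log2 1.26, SE 0.05). With the mean of all probe sets ABCA1 lost its call (log2 0.73, adjusted p = 0.0563), and ETV5 (-1.32) and SPRY1 (-0.72) kept theirs. All 38 were also called in the same direction at 20 mg/kg against vehicle. The 2 comparisons share the 20 mg/kg arrays and each gene's estimate of the spread, so this overlap is not independent evidence.

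MAPK pathway output genes were lower again, with 4 of 17 past the test, DUSP6, IER3, ETV5 and SPRY1 (log2 -1.43, SE 0.08), and 16 when adjusted over the list alone. The list had a mean of -1.99 and an adjusted p of 1.38e-18 (adjusted p = 0.251 with an estimated correlation). FOXO targets were higher as a list (mean 0.47, adjusted p = 1.7e-06; adjusted p = 0.396 with an estimated correlation). None of the 19 passed (7 when adjusted over the list alone), with FBXO32 at log2 1.72 (adjusted p = 0.0922) and BCL2L11 at 1.52 (adjusted p = 0.0812), or -0.01 with its next brightest probe set. Over the alternatives the list mean ran from 0.30 to 0.56 and FBXO32 from 0.78 to 2.13. DNA replication genes were lower as a list (mean -0.47, adjusted p = 1.33e-05; adjusted p = 0.662 with an estimated correlation), with RRM2 at log2 -1.30 and UHRF1 at -1.21. So were ribosome biogenesis genes (mean -0.54, adjusted p = 1.33e-05; adjusted p = 0.454 with an estimated correlation), with WDR43 at -1.75 and UTP15 at -1.41. NF-kB genes (mean -0.61, CXCL8 at -2.73 and IL6 at -2.01), fatty acid synthesis genes (mean -0.38, FASN at -1.31 and MID1IP1 at -0.57), cholesterol synthesis genes (mean -0.25, SQLE at -0.83 and ACAT2 at -0.66) and oxidative phosphorylation genes (mean -0.17, COX5A at -0.41 and ATP5MC3 at -0.33) were lower as lists. Their camera adjusted p was 0.00413, 0.00414, 0.0333 and 0.00153, and with an estimated correlation the adjusted p = 0.662, 0.662, 0.674 and 0.662. Antigen presentation (mean 0.13, GBP2 at 1.51 and TAP2 at -0.44), mesenchymal (mean 0.10, SNAI2 at -0.81 and MMP2 at 0.40) and autophagy and lysosome genes (mean 0.16, ATG14 at 1.01 and ULK1 at 0.49) were higher as lists. Their adjusted p was 0.0075, 0.0192 and 0.0117, and with an estimated correlation the adjusted p = 0.662, 0.508 and 0.674. No member of these 7 lists passed on its own. Several lists called here were not called at 20 mg/kg against vehicle. There the means were 0.04 for antigen presentation, -0.01 for mesenchymal, 0.09 for autophagy, -0.19 for DNA replication and -0.13 for oxidative phosphorylation genes. At 4 mg/kg against vehicle they were -0.09, -0.11, -0.06, 0.28 and 0.04. The 4 mg/kg arrays therefore contribute to these differences, which are not shown to be changes that the higher dose adds.

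Several list means or calls for 20 against 4 mg/kg depended on 1 array compared or on the estimate of the spread. Leaving out either vehicle array changes no mean here, alters only that estimate and gives the same fit as the 4 compared arrays alone. The antigen presentation mean was 0.02 without 4 mg/kg replicate 1 (adjusted p = 0.357) and 0.24 without 4 mg/kg replicate 2. The oxidative phosphorylation mean was -0.10 without 4 mg/kg replicate 2 and with centred arrays, still called. The mesenchymal mean was -0.03 without probe sets that may cross-hybridise and 0.04 with the mean of probe sets, past the test in neither. That call was lost after quantile normalization (0.12), with centred arrays (0.16) and without 4 mg/kg replicate 2 (0.10), 20 mg/kg replicate 1 (0.08) or either vehicle array (0.10). The cholesterol call was lost without either vehicle array (-0.25), 4 mg/kg replicate 1 (-0.35), 4 mg/kg replicate 2 (-0.15) or 20 mg/kg replicate 1 (-0.18), and without probe sets that may cross-hybridise. Among members SQLE was at -0.55 without 4 mg/kg replicate 2, FASN at -0.86 without 20 mg/kg replicate 1 and TAP2 at -0.26 without 4 mg/kg replicate 2. The fatty acid call was lost without 4 mg/kg replicate 2 (-0.28) and the NF-kB call without 20 mg/kg replicate 2 (-0.57). The autophagy mean was 0.10 without 4 mg/kg replicate 1, and its call was lost without 4 mg/kg replicate 2 (0.22) or 20 mg/kg replicate 1 (0.16). With the next brightest probe set 6 of 22 named genes lost their call: KLHL24 (1.83), ABCA1 (1.60), CREBRF (1.14), CX3CL1 (-2.49), ANKRD22 (-0.95) and ETV5 (-2.56).

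In all, camera called 11 lists and fry 6. Only 4 lists were called by both: MAPK pathway output, FOXO targets, ribosome biogenesis and mesenchymal genes. The other 7 lists that camera called had fry adjusted p-values from 0.0615 (fatty acid synthesis) to 0.494 (antigen presentation). The gene count was 0 without vehicle replicate 1, vehicle replicate 2, 4 mg/kg replicate 2 or 20 mg/kg replicate 2, with 1318, 1318, 1631 and 1361 genes at an unadjusted p under 0.05. It was 2 without 20 mg/kg replicate 1 and 218 without 4 mg/kg replicate 1. It was 8 with no level filter and 0 with the replicate number as a block (1472 at an unadjusted p under 0.05). With the 4 arrays alone, the same fit as without either vehicle array, it was 0 (1318 at an unadjusted p under 0.05). It was 77 and 201 without genes tied in all or any groups, 333 after quantile normalization (151 higher and 182 lower) and 494 with centred arrays (227 higher and 267 lower).

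The 2 doses were also set against each other across genes. All 6 genes called at 4 mg/kg were called in the same direction at 20 mg/kg, 3 higher and 3 lower, where independent lists would share 0.0678 and 0.0622. In simulated unchanged groups, taking as many of the smallest p-values at each dose, 4.36 of 6 genes on average (1 to 6) were shared in the same direction, so the 6 lie within that range. Of the 445 genes called at 20 mg/kg, 410 had the same sign at 4 mg/kg and 375 had the same sign and a smaller change. The 445 smallest p-values of simulated unchanged groups gave 377 (359 to 408) and 311 (289 to 339). In those draws limma called 0 genes at either dose. On average 599 genes had an unadjusted p under 0.05 at 20 mg/kg, against 2486 in the data. These draws are therefore unlike the data too. They show that shared vehicle arrays alone can give agreement in sign, but not how much of the observed agreement comes from them. With the effect at 20 mg/kg alone simulated, 258 (234 to 297) had the same sign and 1.97 genes (0 to 5) were shared, but limma called 2390 genes on average there, far from the 445 observed. The covariance of the 2 sets of log2 changes was 0.136 against 0.0149 (0.0132 to 0.0165) for simulated unchanged groups, a difference of 0.121. The correlation across genes was r = 0.739 against 0.501, and 74.2% of genes had the same sign against 66.7%. The simulated groups share the vehicle arrays too, and their r of 0.501 is that of groups with equal spread. In the data the 2 vehicle arrays differed most (SD of the difference 0.303 log2 units, against 0.264 at 4 mg/kg and 0.191 at 20 mg/kg). A noisier vehicle would raise r and the shared signs and calls of unchanged groups. Part of the excess may therefore still come from the vehicle arrays, which cannot be split into parts of 2. The covariance was 0.223 without vehicle replicate 1, 0.0726 with no level filter and 0.0742 with the mean of probe sets.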

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

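Signals in data outside the comparisons were looked for in the probe sets that the annotation gives several genes or none. Of 2903 such probe sets above the level filter, limma called 9 at 20 mg/kg against vehicle, 3 higher and 6 lower, with 436 at an unadjusted p under 0.05. At 4 mg/kg it called 3, all lower. Their genes were not analysed here. Groups of 2 arrays are too small to test for outlying samples.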

How the results depend on the processing

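Leaving out genes with equal values within groups and crossing the replicate numbers were chosen after seeing the data. The 445 genes at 20 mg/kg against vehicle became 57 with no level filter, 285 without probe sets that may cross-hybridise, 136 with the 4 arrays alone, 1536 after quantile normalization, 1958 with centred arrays, and 819 or 1242 without genes tied in all or any groups. The 6 genes at 4 mg/kg became 3 with no filter, 41 after quantile normalization, 766 with centred arrays, 257 without genes tied in any group, and 0 with the stricter filter, the mean of probe sets, array weights, log2(value + 16), every probe set, genes tied in all groups left out or the 4 arrays alone. In those limma fits 1281 to 1885 genes, or 2564 probe sets, had an unadjusted p under 0.05. The 38 genes at 20 against 4 mg/kg became 8 with no filter, 333 after quantile normalization, 494 with centred arrays, 77 or 201 without tied genes and 0 with the 4 arrays alone. With 1 array left out the counts ran from 5 to 802, 0 to 475 and 0 to 218. Leaving out an array of the group not compared gave the same fit as the 4 arrays alone, so those losses come from the estimate of the spread. Apart from this and from fewer arrays or other genes in a fit, causes were not tested. The exceptions are the ties and the array scale weighed under the other observations.

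The replicate numbers are not shown to pair the arrays: deviations of same-numbered arrays correlated at 0.146 for vehicle and 4 mg/kg, -0.118 for vehicle and 20 mg/kg and 0.127 for 4 and 20 mg/kg. With the replicate number as a block the counts were 93, 0 and 0 genes, and with the numbers of the 20 mg/kg group crossed the count at 20 mg/kg was 0, with 2476, 1653, 1472 and 2295 genes at an unadjusted p under 0.05.

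The gene lists called, 12, 8 and 11, all became 0 with an estimated correlation, with 2, 0 and 3 lists at an unadjusted p under 0.05. That test has only the 3 residual degrees of freedom and so little power with these arrays. It also used correlations such as 0.55 for mitosis and 0.41 for hypoxia genes in place of the preset 0.01. Of the lists called with the preset correlation fry kept 10, 0 and 4. fry called 14, 0 and 6, no filter gave 18 at 20 against 4 mg/kg, and the count at 4 mg/kg ran from 5 to 8 with 1 array left out. The covariance of the 2 dose effects, 0.136, moved to 0.0726 with no filter and 0.0742 with the mean of probe sets, and ran from 0.0939 to 0.223 with 1 array left out. Of the named genes that passed, BCL2L11 at 20 mg/kg reversed, to -0.0555 with its next probe set. That choice also turned values that had not passed, at 4 mg/kg CCNE2 to -0.33, CREBRF to -0.13, BCL2L11 to -0.05, ETV5 to 0.01 and EGR1 to 0.05, and at 20 against 4 mg/kg BCL2L11 to -0.01. Signal near the floor limits what can be seen: 39.48% or more of probe sets lay at it in every array.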

Other observations

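The tests of each pattern below, the fits without tied genes and the genes of this paragraph were chosen after the results had been seen, while the gene lists, centred arrays and left-out arrays were fixed before. At 20 mg/kg against vehicle, 2 of 14 genes of the BCL2 family and caspase inhibitors rose, BMF (log2 2.06, SE 0.07) and BCL2L11. The list did not pass camera (adjusted p = 0.571) but passed fry (adjusted p = 0.0353). Among 12 heat shock genes 3 fell, BAG3 (log2 -0.90, SE 0.03), HSPH1 (log2 -0.66, SE 0.08) and SERPINH1 (log2 -0.41, SE 0.05). For the list the adjusted p was 0.158 from camera and 0.0228 from fry. EGFR fell by 0.74 on the log2 scale (SE 0.07) and IGF1R rose by 0.78 (SE 0.08), the 2 of 22 receptor and ligand genes that passed. The keratin gene KRT18 fell (log2 -1.54, SE 0.18) while the desmosome genes DSC2 (log2 0.79, SE 0.09) and DSP (log2 0.55, SE 0.06) rose.

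Hypoxia and glycolysis genes were lower as lists at both doses, though HK2 was lower at 20 mg/kg (log2 -2.28) than at 4 mg/kg (log2 -0.96; adjusted p = 0.0211), or -0.76 and -0.32 as the mean of its probe sets, and BHLHE40 was at -2.16 and -1.29. Vehicle replicate 2, which stood apart, was not the whole cause: without it the hypoxia list's mean was -0.57 at 20 mg/kg and -0.58 at 4 mg/kg, against -0.61 and -0.62 with it, and the glycolysis list's -0.43 and -0.32, with camera adjusted p-values of 4.86e-05 or less. Centring each array on its median moves every gene of a comparison by the same amount, -0.03 at 20 mg/kg and -0.10 at 4 mg/kg. The hypoxia means were then -0.64 and -0.72, with camera adjusted p-values of 0.000224 or less. Centring could not have removed means of this size, so it shows only that an offset between array medians is not their source. It cannot decide whether array scale plays a part beyond such an offset. These use the preset correlation, and no call held with an estimated one. An effect of the drug, a difference in oxygen supply between tumours and a difference in sample handling may each be behind the pattern, and with 2 arrays per group and the 18S control high in both vehicle arrays they stay open and untested.

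Mitosis genes were higher as a list at 4 mg/kg, with a mean of 0.54 and none of 27 past the test. Without 4 mg/kg replicate 2, whose median over tested genes was the highest of the 6 arrays, the mean was 0.34 with a camera adjusted p of 0.00277, so that array adds to the pattern without being all of it. With centred arrays the mean was 0.44 (camera adjusted p = 2.93e-08). Centring moves every gene of this comparison by -0.10, so it could not have removed a mean of 0.54. It cannot decide whether array scale plays a part beyond an offset between array medians. The drug at this dose and differences between tumours may both be behind it, and neither was tested. With an estimated correlation the adjusted p was 0.88.

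The number of called genes rose with centred arrays, from 445 to 1958 at 20 mg/kg, from 6 to 766 at 4 mg/kg and from 38 to 494 for 20 against 4 mg/kg. Equal values within groups, which rescaling breaks, are a candidate cause: leaving out the 531 genes tied in all groups, with no rescaling, gave 819 at 20 mg/kg and 77 for 20 against 4 mg/kg. At 4 mg/kg this stays open, since limma then called 0 genes (1885 at an unadjusted p under 0.05) but 257 without genes tied in any group. The prior degrees of freedom, 0.723 in the main fit, were 1.44 without genes tied in all groups and 3.55 without genes tied in any. With centred arrays they were 4.97, and with no level filter, which gave 57 genes at 20 mg/kg, 0.322. The main counts were thus made with little moderation, which the ties lower. Among genes without ties centring took the count from 257 to 693 at 4 mg/kg and from 201 to 440 for 20 against 4 mg/kg, so array scale is a candidate cause there too. At 20 mg/kg it went from 1242 to 1818, 1.46 times, below the limit of 1.5 first set, but a margin of 10% was added once this ratio had been seen, and as the ratio has no measured spread the share of array scale stays open.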
